A study of Mus musculus with 4 samples.

How the data were processed

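Microglia, the resident macrophages of the brain, were profiled by droplet single-cell RNA sequencing (10x Genomics Chromium) in 4 libraries from C57BL/6 mice. Whole-brain irradiation was given as a single dose of 8 Gy at postnatal day 21, and sham mice were handled as controls without a dose, per the labels and the design text. Each library was a pool of 4 mice, and there was 1 library for each of the groups sham at 6 h, irradiated at 6 h, sham at 1 week and irradiated at 1 week. Other times after irradiation that the design text mentions were not analysed here.

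The deposited matrices hold raw UMI counts per gene and cell barcode, where a UMI is a molecular tag that counts each captured transcript once. They were made with Cell Ranger 2.0 on the mouse build mm10, per the submitters' processing notes. The barcode threshold and the annotation release are not given in the sources used here. Of 27998 gene identifiers, 27645 were matched by identifier to the GENCODE vM21 annotation of GRCm38 (mm10), from which coordinates were taken. The sex of the mice is not given in the labels used here.

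The files held 8486 barcodes, and the design text states 8095 cells. Barcodes were kept from 1000 UMIs and 500 detected genes with at most 10% mitochondrial UMIs, which left 8369. The filter removed 18 barcodes of the sham library at 6 h, 37 of the irradiated library at 6 h, 41 of the sham library at 1 week and 21 of the irradiated library at 1 week. Doublets were called per library with Scrublet as built into scanpy 1.11.5 at an expected rate of 0.06. It marked 54 barcodes, or 0.645%, far below that rate, and 8315 cells remained. Doublets that the caller missed can therefore remain among the cells.

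The cells of all libraries were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm (leidenalg 0.10.2) at resolution 1. Clusters were named from marker genes of 17 classes that were fixed before the data were examined. The rule that turned markers into names was set after the clusters had been seen. A marker counted from 50 CPM, and microglia-like clusters needed 7 of 9 microglia markers at that level. Other immune classes and the erythroid class needed 3 markers at least 1.5-fold above the other cells. Neural, ependymal and vascular classes could not be named by this rule, however many of their markers were higher. A cluster with higher markers of several neural or vascular classes at once was left unnamed and is called mixed here. Different clusters held the largest part of the microglia-like cells of the 4 libraries, namely cluster 0 for sham at 6 h, clusters 2 and 5 for irradiated at 6 h, cluster 3 for sham at 1 week and cluster 1 for irradiated at 1 week. These clusters therefore largely followed the libraries, while others, such as clusters 4 and 7, were spread over several libraries. Neither cluster sizes nor their leading genes are reported as results.

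With 1 library per group there is no replicate check and no test, so no p-value or standard error is given. UMIs were summed over the microglia-like cells of each library and scaled to the library total (CPM). A log2 fold carries the exact conditional binomial 95% interval, a share of cells the exact Clopper-Pearson 95% interval, and both cover counting error only. A count of 0 was put at 3 counts and the fold written as a bound. Such a bound, given as "at least", is a convention, and the exact interval can reach lower. On simulated counts drawn from these libraries the fold intervals held the true value for 94.8% of 9882 genes at 6 h, 95.3% of 9480 genes at 1 week and 94.5% of 9669 genes between the sham libraries. Of 50 genes given a true fold of 2, 98% were found past 1.5-fold at 6 h. The share was 100% at 1 week and 96% between the sham libraries. The simulated counts held counting error only, so these values check the calculation and not the spread between cells or mice. For genes with uneven counts over cells, such as Ccl4, the intervals are too narrow even for the sampling of cells.

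Before the data were examined, 21 gene lists were fixed: p53 targets, homeostatic microglia, disease-associated microglia, inflammatory cytokines and NF-kB, interferon response, MHC class I, MHC class II, S phase, G2/M phase, DNA repair, apoptosis, complement and phagocytosis, lysosome, dissociation and immediate early, glycolysis, oxidative phosphorylation, translation, cholesterol and lipid, TGF-beta signalling, senescence, and sex-linked genes. They hold 717 symbols, of which 5 were not matched and 2 were matched by an older symbol. Some genes stand in several lists. A member was measured from 50 UMIs over both libraries of a comparison. Each list is given by its median log2 fold with the order-statistic 95% interval over its members, by the number of members at least 1.5-fold higher or lower, and by the percentile of its median among 10000 random lists of the same size, matched in 20 bins of expression. The percentile describes these libraries and is not a test across mice. Among 100 simulated lists without a change, 6 at 6 h, 15 at 1 week and 11 between the sham libraries lay outside the 5th to 95th percentiles.

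Named genes followed a rule fixed before the data were examined: per comparison the 12 with the highest and the 12 with the lowest log2 fold by the interval bound nearest 0 among genes with 100 or more UMIs, up to 4 members with the largest absolute fold per list, 21 genes named in advance, and the sex-linked list. For the per-cell results each microglia-like cell was thinned at random to 2000 UMIs, and shallower cells were left out. These were 84 cells (3.20%) of sham at 6 h, 51 (2.68%) of irradiated at 6 h, 189 (12.2%) of sham at 1 week and 102 (4.80%) of irradiated at 1 week. A cell counted as past the sham limit of a list when its list UMIs lay above the 95th percentile of the sham library of the same time. For the homeostatic list the limit was the 5th percentile and cells below it were counted, a choice made after the data had been seen, as were the per-cell values of single genes and their variance over mean. Pairs of lists were compared with shared genes left out.

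Alternatives fixed in advance covered the scaling, the sum over cells, thinning, the cell filter, doublets, the clustering resolution, the UMI minimum of list members and the per-cell limits. Settings added after the data had been seen used the sham library of the other time as control, left out the most abundant member of a list, or left out Gtse1 and Psrc1 from the G2/M list. A further pair of settings that left out interferon-rich and immediate-early-rich clusters was computed and then dropped, because it selected cells by the outcome. A further test of the mixed cells is not reported here. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.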

Results

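The series profiled single microglia from the brains of young mice after a single whole-brain dose of 8 Gy, next to sham mice. The labels give the source as brain and the design text speaks of hippocampal microglia, so the region behind all values is not settled here. Its stated question was whether genes that respond to irradiation are expressed together in the same microglia or whether the cells are heterogeneous. The sham library at 6 h held 2670 barcodes and 9760928 UMIs, and the irradiated library at 6 h held 2023 barcodes and 7399019 UMIs. The sham library at 1 week held 1623 barcodes and 5706955 UMIs, and the irradiated library at 1 week held 2170 barcodes and 7733309 UMIs. Median depth per barcode was alike, at 3528, 3497, 3570 and 3422.5 UMIs in the same order. Each group was 1 library pooled from 4 mice, so every difference below has no replicate check, and the 95% intervals of genes and of shares of cells cover counting error only. The intervals of list medians are over the members of a list and describe the spread of its genes.

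Nearly all kept cells were microglia-like, with the markers P2ry12, Tmem119, Csf1r and C1qa. Their share was 99.2% (2625 of 2645 cells, interval 98.8 to 99.5%) in sham at 6 h and 96.2% (1902 of 1978, 95.2 to 97.0%) in irradiated at 6 h. At 1 week it was 99.7% (1551 of 1556, 99.3 to 99.9%) in sham and 99.5% (2126 of 2136, 99.1 to 99.8%) in irradiated. The remaining cells were monocyte-like (5, 8, 1 and 2 cells in the order above), border macrophage-like (7, 4, 2 and 1 cells) or mixed. Mixed cells, which a threshold set after seeing the data kept out of the microglia-like class, made up 0.302% (8 cells), 3.24% (64 cells), 0.129% (2 cells) and 0.328% (7 cells). The class did not hold the same kinds of cells in every library. Under a stricter cell filter the microglia-like share of irradiated at 6 h was 98.7% and its mixed share 0.749%.

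The first comparison asked what irradiation did to microglia within 6 h. Targets of p53, the transcription factor of the DNA damage response, were the most raised list, with a median log2 fold of 1.98 (interval over members 1.02 to 3.09) and 27 of 34 measured members at least 1.5-fold higher against 1 lower. Its median was at percentile 100 of random lists, while between the sham libraries it was -0.010. Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, mm10 chromosome 17, 29090976 to 29100727), went from 505 UMIs in sham to 21326 in irradiated cells, a log2 fold of 5.83 (5.71 to 5.96). Phlda3, a repressor of Akt signalling (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136), had 6 and 2511 UMIs, a log2 fold of 9.14 (8.02 to 10.59). The gene for the p53 ligase Mdm2 (chromosome 10, 117688875 to 117710758) stood at 2.29 (2.14 to 2.44). Of the cell death genes in the list, Bax (chromosome 7, 45461697 to 45466898) was at 2.37 (2.28 to 2.46), Bbc3 at 3.18 (2.97 to 3.40) and Fas at 3.73 (3.01 to 4.54). Outside the p53 list, Gdf15, a stress-induced cytokine gene of the senescence list (chromosome 8, 70629393 to 70632456), had 19 and 2715 UMIs, a log2 fold of 7.59 (6.95 to 8.33).

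Genes of the homeostatic microglia list were lower at 6 h, with a median of -0.44 (-0.60 to -0.15) and 11 of 34 members at least 1.5-fold lower against 1 higher, at percentile 0. The purinergic receptor gene P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871) was at -1.16 (-1.19 to -1.14), with 63747 UMIs in sham and 21061 in irradiated cells. The fructose transporter gene Slc2a5 was at -1.41 (-1.497 to -1.33) and Sall1, a transcription factor gene of microglial identity, at -1.08 (-1.23 to -0.93). Other markers stayed close to sham, with Tmem119 at -0.026 (-0.05 to 0.0015) and Cx3cr1 at -0.15 (-0.18 to -0.12). Csf1r, the receptor that microglia need for survival, was at -0.54 (-0.57 to -0.52). Between the sham libraries the list median was 0.016.

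Inflammatory cytokines and NF-kB genes were higher at 6 h, with a median of 0.70 (0.12 to 1.75) and 18 of 36 members at least 1.5-fold higher against 1 lower, at percentile 100. The chemokine genes Ccl4 (ENSMUSG00000018930, chromosome 11, 83662584 to 83664683) and Ccl3 (chromosome 11, 83647844 to 83649355) were at 2.78 (2.73 to 2.83) and 2.30 (2.24 to 2.36). Ccl7 was at 2.56 (2.21 to 2.92), Cxcl16 at 2.57 (2.42 to 2.73), Ccl2 at 1.84 (1.72 to 1.96) and Tnf at 2.18 (1.90 to 2.48). Il1b had few UMIs, 18 in sham and 52 in irradiated cells, a log2 fold of 1.96 (1.17 to 2.83). The list was also higher in sham at 1 week than in sham at 6 h, by a median of 0.25 with 10 of 35 members at least 1.5-fold higher. Against the sham library at 1 week the 6 h median was 0.26 and Il1b stood at -0.60. After thinning to equal depth, Tnf had a UMI in 7.67% of irradiated cells at 6 h, 2.09% of sham cells at 6 h and 5.36% of sham cells at 1 week. Disease-associated microglia genes had a median of 0.56 (0.18 to 1.02), with 17 of 34 members higher and 1 lower, against -0.086 between the sham libraries. Examples were Lilrb4a at 3.93 (3.26 to 4.69), the galectin gene Lgals3 at 2.55 (2.23 to 2.89) and Csf1 at 1.75 (1.503 to 2.01), whereas Apoe was at -0.36 (-0.39 to -0.33). Between the sham libraries Apoe was at -1.13, and against the sham library at 1 week it stood at 0.77.

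Interferon response genes were higher at 6 h, with a median of 0.72 (0.38 to 0.93), at percentile 100. Of 45 members, 26 were at least 1.5-fold higher and 2 lower. The sham libraries lay as far apart for this list, with a median of -0.75 (-1.36 to -0.58) for sham at 1 week over sham at 6 h. There 28 of 44 members were lower. Isg15, a ubiquitin-like protein gene, was at 1.45 (1.30 to 1.59), the antiviral gene Rsad2 at 1.79 (1.47 to 2.12) and Gbp2 at 1.69 (1.31 to 2.08). The MHC class I list had a median of 0.13 (-0.26 to 0.72) with 5 of 17 members higher and 0 lower, among them H2-K1 at 1.62 (1.56 to 1.67) and H2-Q7 at 2.26 (1.97 to 2.55). H2 genes are near-identical paralogs, so their single values are uncertain. In the MHC class II list the median was -0.31 (-0.87 to 2.46), with 2 of 7 members higher and 1 lower. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), was at 2.46 (2.33 to 2.59) and H2-Ab1 at 0.73 (0.36 to 1.11). H2-Ab1 was at 1.70 over all barcodes and at 0.27 against the sham library at 1 week. Markers of several other cell types had intervals apart within the microglia-like cells at 6 h. Here and at 1 week such sums do not tell other cells from expression by microglia. In irradiated microglia-like cells at 6 h, 55.8% carried an astrocyte marker UMI, 47.6% a neutrophil, 13.2% a B cell and 11.2% a monocyte marker UMI. For NK cell and oligodendrocyte precursor markers the shares were 1.84% and 0.894%. Monocyte markers summed to 37.7 CPM (33.9 to 41.8) in sham and 57.6 CPM (52.2 to 63.5) in irradiated cells, astrocyte markers to 146 (139 to 154) and 248 (236 to 260), and B cell markers to 89.8 (83.9 to 95.9) and 39.7 (35.2 to 44.6). NK cell markers were at 15.6 (13.2 to 18.3) and 5.04 (3.53 to 6.97), border macrophage markers at 19.98 (17.3 to 23.01) and 12.9 (10.4 to 15.8), endothelial markers at 29.2 (25.9 to 32.8) and 21.1 (17.9 to 24.8), neutrophil markers at 153.8 (146.1 to 161.9) and 177 (168 to 187), oligodendrocyte precursor markers at 0.414 (0.113 to 1.06) and 2.80 (1.71 to 4.32), and erythroid markers at 2.28 (1.43 to 3.45) and 0.140 (0.00354 to 0.779).

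Cell cycle genes were lower at 6 h. The G2/M list had a median of -0.95 (-1.57 to -0.28), with 23 of 36 members at least 1.5-fold lower and 4 higher, and the S phase list had -0.40 (-0.61 to -0.17), with 10 of 28 lower and 1 higher. Top2a, the topoisomerase of dividing cells (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189), was at -1.97 (-2.62 to -1.37) from 143 and 27 UMIs, and Mki67 (chromosome 7, 135689784 to 135716361) at -1.97 (-3.11 to -0.98). Among the members that were higher were Gtse1 at 4.71 (3.54 to 6.18) and Psrc1 at 4.28 (3.43 to 5.26), both also members of the p53 list. The sham library at 1 week was itself lower than the sham library at 6 h, with medians of -0.97 for G2/M and -0.21 for S phase. Against that other sham library the G2/M median at 6 h was -0.054 and the S phase median -0.10. Against the sham library at 6 h, the G2/M median was -0.31 with members counted only from 200 UMIs and -1.28 from 20 UMIs.

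**Figure D1:**
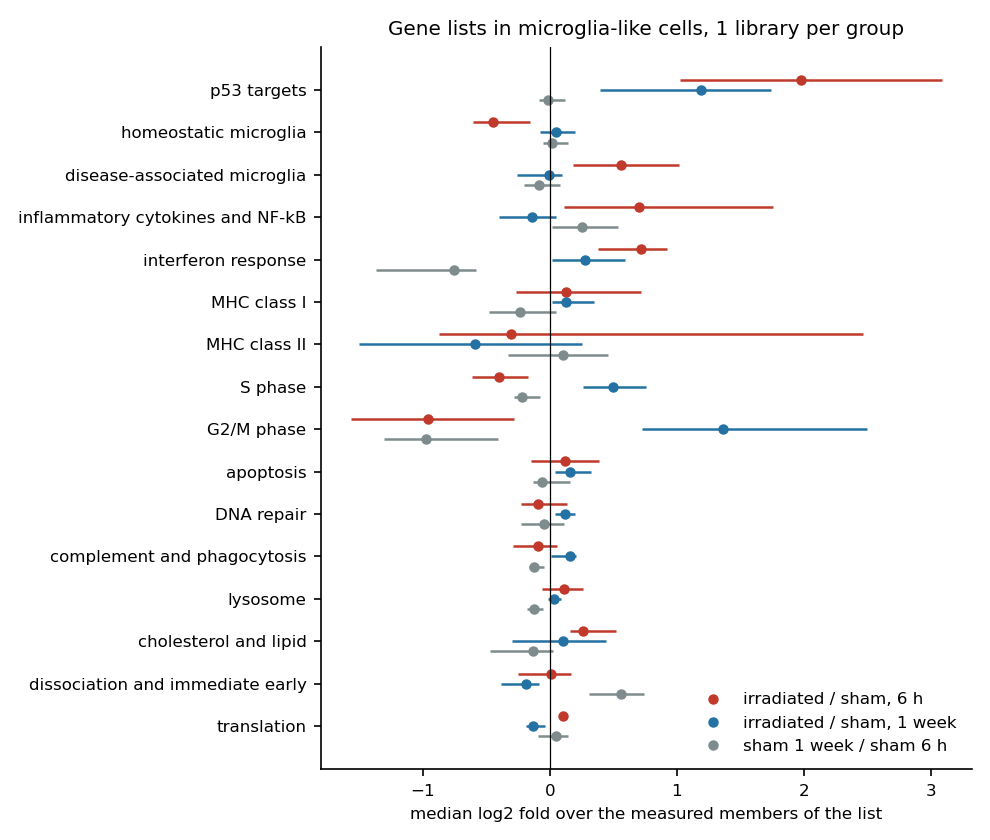
Median log2 fold (points) and its order-statistic 95% interval over members (lines) for 16 gene lists in microglia-like cells, for irradiated over sham at 6 h, irradiated over sham at 1 week, and sham at 1 week over sham at 6 h. The p53 list lies at 1.98 and 1.19 in the irradiation comparisons and at -0.010 between the sham libraries.

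The second comparison asked what was left of the response at 1 week. The p53 target list was still higher, with a median of 1.19 (0.40 to 1.74) and 20 of 31 members at least 1.5-fold higher against 2 lower, at percentile 100. Cdkn1a had 314 UMIs in sham and 16892 in irradiated cells, a log2 fold of 5.29 (5.13 to 5.45). Phlda3 was at 7.01 (5.78 to 8.63), Ccng1, the gene of cyclin G1, at 2.52 (2.20 to 2.86), Bax at 1.74 (1.63 to 1.86) and Mdm2 at 1.19 (0.98 to 1.40). Gdf15 was at 1.21 (0.56 to 1.91), from 26 and 83 UMIs. Epha2, an ephrin receptor gene outside the lists, had 2.42 (2.00 to 2.86), next to 2.62 (2.26 to 2.99) at 6 h.

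**Figure D2:**
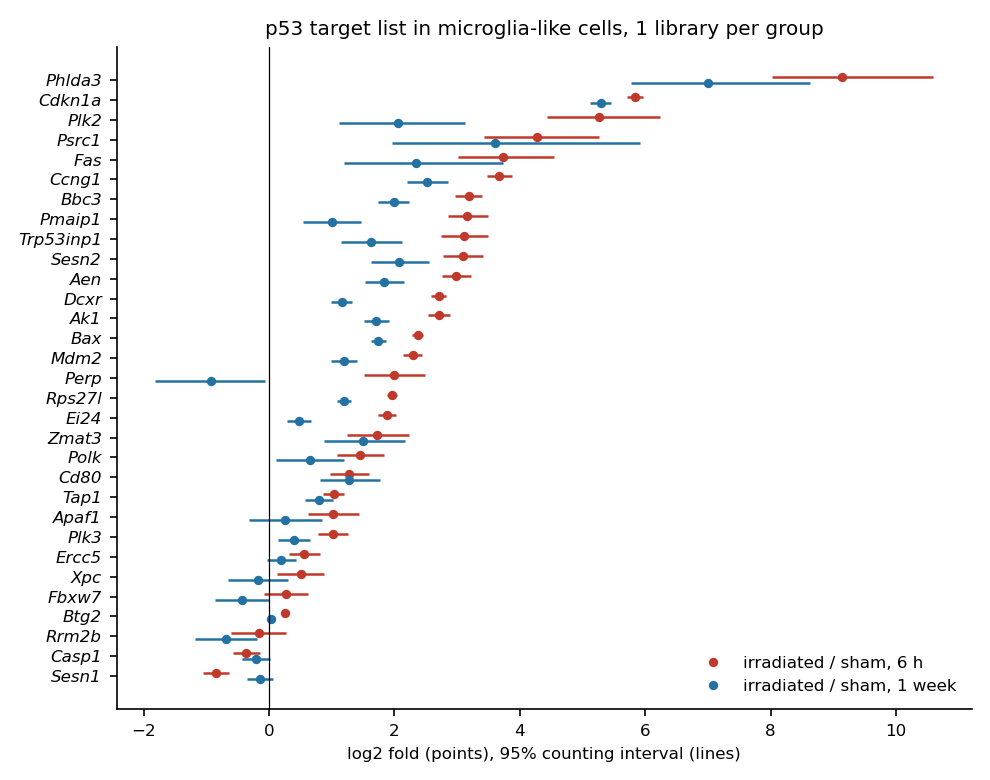
Log2 fold of irradiated over sham (points) with the 95% counting interval (lines) for the 31 p53 target genes measured at both times, in microglia-like cells of 1 library per group. Cdkn1a lies at 5.83 at 6 h and 5.29 at 1 week.

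Homeostatic genes were close to sham at 1 week, whereas inflammatory genes differed in both directions. The homeostatic list had a median of 0.046 (-0.08 to 0.20), and 0 of 34 members were 1.5-fold higher or lower. P2ry12 was at 0.32 (0.30 to 0.34) and Slc2a5 at 0.32 (0.26 to 0.39), while Csf1r was at -0.45 (-0.48 to -0.42) and Cst3, the cystatin C gene, at -0.51 (-0.52 to -0.50). The inflammatory list had a median of -0.14 (-0.40 to 0.05), with 4 of 35 members higher and 7 lower, at percentile 0.02. Ccl4 was at -0.53 (-0.59 to -0.48), Ccl3 at -0.76 (-0.83 to -0.69) and Cxcl10 at -1.33 (-1.69 to -0.97), but Ccl2 was at 1.36 (1.21 to 1.51) and Ccl7 at 1.25 (0.75 to 1.79). Ccl4 and Ccl3 were 1.27 and 1.26 higher in sham at 1 week than in sham at 6 h, and against the sham library at 6 h they stood at 0.74 and 0.51 and the list at 0.34. The disease-associated list had a median of -0.0094 (-0.26 to 0.10), with 2 of 28 members higher and 4 lower, among them Lgals3 at -2.56 (-3.47 to -1.73) from 64 and 15 UMIs.

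Interferon response genes had a median of 0.28 (0.02 to 0.59) at 1 week, with 13 of 39 members at least 1.5-fold higher and 1 lower. Ifitm3 (chromosome 7, 141009586 to 141010770) was at 1.27 (0.98 to 1.56) and Oasl2 at 1.79 (1.12 to 2.53). Both were far lower in sham at 1 week than in sham at 6 h, at -2.27 and -3.13, and the list as a whole was at -0.75 (-1.36 to -0.58) between the sham libraries, with 28 of 44 members lower. Against the sham library at 6 h the 1 week median of the list was -0.63, with Ifitm3 at -1.005 and Oasl2 at -1.33. MHC class I genes had a median of 0.13 (0.01 to 0.35) with 3 of 17 members higher and 0 lower, and -0.081 against the sham library at 6 h. MHC class II genes had a median of -0.58 (-1.497 to 0.25) with 3 of 7 members lower and 0 higher, with Cd74 at -1.43 (-1.73 to -1.14) and H2-Ab1 at -1.497 (-2.07 to -0.95). Monocyte markers in the microglia-like cells were at 17.9 CPM (14.5 to 21.8) in sham and 17.3 CPM (14.5 to 20.5) in irradiated cells at 1 week, whereas astrocyte markers were at 143 (133 to 153) and 180.1 (171 to 190), border macrophage markers at 12.6 (9.86 to 15.97) and 22.7 (19.4 to 26.3), NK cell markers at 19.1 (15.7 to 23.2) and 9.43 (7.38 to 11.9) and neuron markers at 0.542 (0.112 to 1.58) and 2.75 (1.70 to 4.21).

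Cell cycle genes were higher in irradiated microglia at 1 week. The G2/M list had a median of 1.36 (0.73 to 2.49), with 30 of 39 members at least 1.5-fold higher and 0 lower, and the S phase list 0.49 (0.26 to 0.76), with 12 of 31 higher and 0 lower, both at percentile 100. Top2a had 12 UMIs in sham and 268 in irradiated cells, a log2 fold of 4.02 (3.19 to 4.99), and Mki67 had 11 and 119 UMIs, a log2 fold of 2.97 (2.08 to 4.01). Ube2c was at 2.36 (1.71 to 3.08) and Nusap1, from 2 and 65 UMIs, at 4.56 (2.65 to 7.64). Rrm2, a subunit gene of ribonucleotide reductase, had 0 and 92 UMIs. With 3 counts in place of 0 it was 22.2-fold higher, and the exact interval reaches lower. Against the sham library at 6 h the G2/M median was 0.70. Against the sham library at 1 week it was 0.45 with members counted from 200 UMIs and 2.26 from 20 UMIs.

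Over 8119 genes the log2 folds at 6 h and at 1 week, each against its own sham library, had a Pearson correlation of 0.330 and a Spearman correlation of 0.078 across genes, which are not independent replicates. The sign was the same for 50.2% of genes. The median absolute log2 fold over 8089 genes was 0.226 at 6 h, 0.151 at 1 week and 0.156 between the sham libraries, the 95th percentiles were 0.905, 0.550 and 0.567, and the 99th percentiles 1.59, 0.969 and 0.894. The sham libraries differ in age and library.

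Per cell, the share of irradiated cells past the sham limit was larger for p53 targets than for inflammatory genes at 6 h. After thinning, 81.3% of irradiated cells at 6 h (1504 of 1851, 79.4 to 83.0%) lay above the sham limit of the p53 list, against 4.37% of sham cells, and at 1 week 32.3% (653 of 2024, 30.2 to 34.3%) against 4.41%. Without thinning the shares were 75.6% and 30.6%, and with the 99th sham percentile as the limit they were 42.1% (39.8 to 44.4%) and 10.9% (9.55 to 12.3%). Btg2, the most abundant member, is also an immediate early gene, and without it the shares were 97.6% and 68.9%. Cdkn1a alone had a UMI in 95.5% of irradiated cells at 6 h (94.4 to 96.4%) against 5.79% in sham, and in 86.1% at 1 week (84.5 to 87.5%) against 6.68%. Without thinning these shares were 98.3, 9.52, 91.3 and 9.74%. No class of irradiated cells is known to lack Cdkn1a, and a UMI was found in 6 of 8 monocyte-like cells of the irradiated library at 6 h. Free RNA in droplets was therefore gauged with P2ry12, which had a UMI in 1 of those 8 cells (12.5%, 0.316 to 52.7%, median depth 3103.5 UMIs) and in 96.7% of its microglia-like cells (median depth 3546.5 UMIs). Tmem119 had a UMI in 2 of the 8 cells. Among the 4 border macrophage-like cells of that library (median depth 5177 UMIs) P2ry12 had a UMI in 3 and Tmem119 in 2, so the background rests on few cells and differed between classes.

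In irradiated cells at 6 h, 24.0% (22.1 to 26.1%) lay above the sham limit of the inflammatory list, against 4.998% of sham cells, and 22.2% (20.3 to 24.1%) lay below that of the homeostatic list, against 4.92%. Without thinning these shares were 21.98% and 12.5%, and with the 99th percentile of sham, or its low counterpart for the homeostatic list, they were 9.13% and 6.48%. The interferon list was passed by 7.89% (6.70 to 9.21%), the disease-associated list by 9.13% (7.86 to 10.5%), MHC class I by 11.5% (10.1 to 13.05%) and MHC class II by 6.54% (5.45 to 7.76%), against sham shares of 4.68, 4.84, 4.88 and 2.20%. Without thinning the irradiated shares were 7.94, 8.83, 11.3 and 10.4% and the sham shares 4.84, 4.99, 4.80 and 4.11%. With the 99th sham percentile as the limit the disease-associated share was 1.13% (0.704 to 1.73%) against 0.984% in sham, the interferon share 3.19%, MHC class I 2.38% and MHC class II 3.51%, and without its most abundant member MHC class II was at 14.3% against 3.97% in sham. At 1 week the shares were 3.85% for the inflammatory, 9.58% for the interferon, 2.77% for the disease-associated, 7.91% for the MHC class I and 2.17% for the MHC class II list, against sham shares of 4.63, 4.55, 4.92, 3.89 and 2.496%. Without thinning the irradiated shares were 4.47, 8.70, 3.39, 7.38 and 4.94% and the sham shares 4.90, 4.19, 4.96, 4.45 and 4.64%. With the 99th sham percentile the 1 week shares were 0.247, 2.32, 0.346, 2.42 and 0.889%, against 0.661% in sham for MHC class II and 0.954% for the others. For the homeostatic list the 1 week share was 9.98% against 4.92% in sham, but 3.39% against 4.96% without thinning, 1.68% against 4.85% without Cst3 and 1.14% against 0.881% at the stricter limit. Ccl4 had a UMI in 44.7% of irradiated cells at 6 h against 14.8% in sham, and 52.997% against 20.3% without thinning. Its variance was 33.2 times its mean over irradiated cells at 6 h and 32.1 times in sham cells, where 1 is the value of counting error alone. For Cdkn1a the values were 3.48 and 3.501 and for Gdf15 11.3 and 5.66. This ratio depends on the mean count, which was 4.43 UMIs in irradiated and 0.684 UMIs in sham cells for Ccl4, and does not rank how uneven the libraries were. In irradiated cells at 6 h the p53 targets Phlda3, Ccng1 and Bax had 1.202, 1.06 and 1.05. The median P2ry12 count was 5 UMIs per irradiated cell at 6 h against 13 in sham, and 14 against 11 at 1 week.

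**Figure D3:**
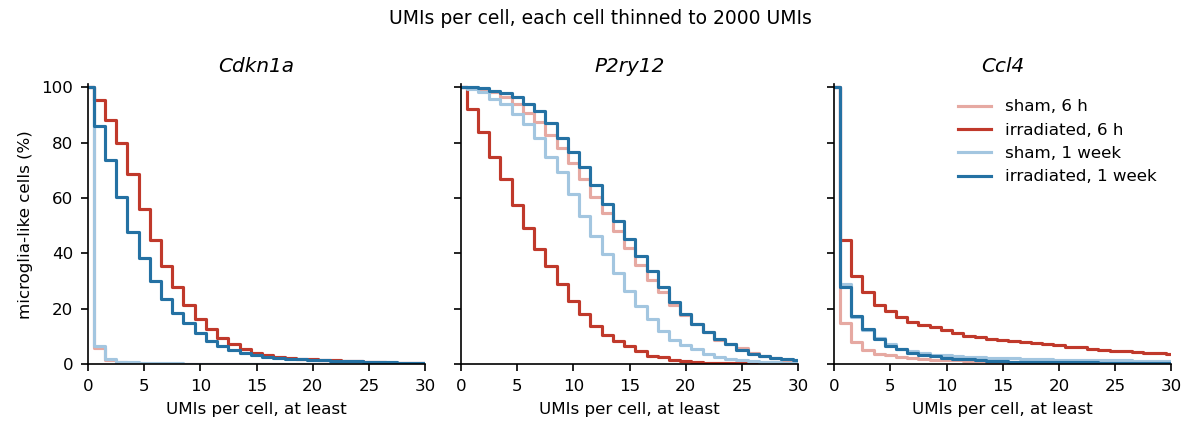
Share of microglia-like cells (vertical axis, percent) with at least a given number of UMIs (horizontal axis) of Cdkn1a, P2ry12 and Ccl4, each cell thinned to 2000 UMIs, with 1 line per library. Cdkn1a had a UMI in 95.5% of irradiated cells at 6 h and Ccl4 in 44.7%.

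Pairs of lists address the question of joint expression. At 6 h, 18.0% of irradiated cells (16.3 to 19.8%) were past the limits of both the p53 and the inflammatory list, where the product of the single shares was 19.5%, and the Spearman correlation over cells was -0.048 in irradiated and 0.21 in sham cells. Cells low for the homeostatic list and high for the inflammatory list made up 12.1% (10.6 to 13.7%), where the product was 5.33%, with a correlation of -0.42 against -0.22 in sham cells. Interferon and MHC class I genes were both high in 4.43% (3.54 to 5.47%) against a product of 0.948%. Their correlation was 0.36 in irradiated and 0.31 in sham cells, so these lists went together without irradiation as well. Inflammatory and interferon genes were both high in 4.75% (3.83 to 5.82%) against 1.90%, with a correlation of 0.15 in irradiated and 0.056 in sham cells. Disease-associated and inflammatory genes were both high in 3.35% (2.58 to 4.27%) against 2.14%, with a correlation of 0.39 in irradiated and 0.13 in sham cells. At 1 week the p53 and inflammatory lists were both high in 2.96% (2.27 to 3.80%) against a product of 1.24%, with a correlation of 0.20 in irradiated and 0.27 in sham cells. Btg2, which is also an immediate early gene, was kept in the p53 list for these pairs. In sham cells the p53 list averaged 3.98 UMIs per cell at 6 h and 1.96 without Btg2, and 5.64 and 1.94 at 1 week. Pairs without Btg2 were not computed, so its part in the values of the p53 pairs is not known. Correlations over cells describe single libraries, and cells are not replicates.

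Shares of cells with cell cycle UMIs depended on the minimum. With 3 or more G2/M UMIs they were 10.6% (9.42 to 11.8%) in sham and 10.0% (8.72 to 11.5%) in irradiated cells at 6 h, and 8.44% (7.02 to 10.0%) and 9.98% (8.71 to 11.4%) at 1 week. Without Gtse1 and Psrc1, which are also in the p53 list, they were 10.5% and 8.86% (7.60 to 10.2%) at 6 h, and 8.44% and 9.63% at 1 week. The other G2/M shares given here include both genes. For S phase they were 12.003% (10.8 to 13.3%) and 10.2% (8.82 to 11.6%) at 6 h, and 10.5% (8.92 to 12.3%) and 13.2% (11.8 to 14.8%) at 1 week. With 5 or more G2/M UMIs the shares were 1.61% and 1.46% at 6 h, and 0.514% (0.207 to 1.06%) and 2.27% (1.67 to 3.02%) at 1 week. Cells under 2000 UMIs were left out as given for the thinning, and unthinned shares at 3 or more G2/M UMIs were 30.7, 33.6, 26.6 and 25.9%. Hmgb2 and Slbp, the most abundant members, are also expressed outside division, and no cell was called cycling from these lists alone.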

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

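The tests that set a library against the sham library of the other time, those of mixed cells by depth, by precursor markers and by mitochondrial share, and the rules that voided the astrocyte and precursor tests were chosen only after the results were seen. The differences between times below were not tested, since each group was 1 library.

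Several genes lay on opposite sides of sham at 6 h and at 1 week, with counting intervals apart from 0 at both times, each against the sham library of its own time. The log2 fold at 1 week minus that at 6 h was -3.06 for Ccl3, -3.31 for Cxcl10, -3.40 for Il1b, -2.62 for Csf1 and -2.81 for Atf3. Among phagocyte and antigen presentation genes it was -5.11 for Lgals3, -5.59 for Lilrb4a, -3.89 for Cd74 and -2.23 for H2-Ab1. Cell cycle genes went the other way, with 5.99 for Top2a, 4.94 for Mki67, 4.75 for Ube2c, 8.71 for Nusap1 and 2.25 for Mcm6, and at least 5.46 for Rrm2. List medians differed by 2.32 for G2/M, 0.89 for S phase, 0.12 for oxidative phosphorylation and -0.24 for translation. The opposite sides depended on the sham library for some of these: against that of the other time Ccl3 at 1 week was at 0.51, Il1b at -0.60 at 6 h and 1.12 at 1 week, Top2a at 6 h at 0.80, Rrm2 at 6 h at least 2.22 higher, Atf3 at 1 week at -0.019, and the oxidative phosphorylation median at 0.032 and -0.040. For others 1 side came closer to 0, with Mki67 at -0.51, Nusap1 at -0.37, Mcm6 at -0.46 and H2-Ab1 at 0.27 at 6 h, Cxcl10 at -0.60 at 1 week, and medians at 6 h of -0.10 for S phase and -0.054 for G2/M. Lilrb4a, too low for that setting at 1 week, had 14 UMIs (1.83 CPM) in irradiated cells at 1 week and 19 UMIs (1.97 CPM) in sham at 6 h.

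The cell cycle pattern was lower G2/M genes at 6 h and higher ones at 1 week, each against its own sham library. A candidate explanation is the sham libraries themselves, since G2/M genes were higher in sham at 6 h than in sham at 1 week. For 6 h this stays open and would be enough, because against the sham library at 1 week the G2/M median was -0.054 (-0.41 to 0.31). For 1 week the median against its own sham library was 1.36 (0.73 to 2.49). Against the sham library at 6 h it was 0.70 (0.29 to 0.87), and with cells thinned to equal depth 0.89 (0.55 to 1.84). The list median and its interval over members thus stayed positive against either sham library and at equal depth. These intervals describe the spread of genes and not of libraries. The tests therefore cannot decide whether the choice of sham library, or depth, was the whole source. Either may account for a part or the whole of the size, and both together were not tested. With 1 library per group, an effect of irradiation cannot be told apart from other differences between libraries. Biological regrowth after irradiation stays open as an untested explanation.

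Interferon genes were higher after irradiation at 1 week and lower in sham at 1 week than in sham at 6 h. A low level in that sham library may account for the 1 week result, since against the sham library at 6 h the median was -0.63 (-0.92 to -0.34). The difference between the sham libraries was not 1 common factor over all cells: such a factor would have left 5.50% of sham cells at 1 week with 10 or more interferon UMIs, where 1.98% (1.31 to 2.87%) had them, against 8.93% in sham at 6 h. The medians were 2 UMIs in both. Age and library are confounded between the sham groups. Which sham library departed from the usual level, and why the libraries differed in a part of the cells, stays open.

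Mixed cells made up 3.24% of kept cells in irradiated at 6 h and were outside every comparison. Doublets of microglia with other cells are argued against by their depth, as the ratio of their median UMIs to that of microglia-like cells was 0.468 (0.416 to 0.576). For free RNA, the prediction written before was a ratio of astrocyte marker UMIs per cell below 3, which was met at 1.26 (0.98 to 1.59). Such a UMI was carried by 55.8% of microglia-like cells but by 15.6% of mixed cells (10 of 64). The ratio of means therefore hides an uneven spread over the mixed cells and decides nothing. Oligodendrocyte precursor markers, at 65.4 times (37.7 to 117) the UMIs per cell, decide nothing either, because higher neural markers were what named these cells mixed. The same holds for neuron markers at 65.4 times (29.7 to 155) and oligodendrocyte markers at 6.18 times (4.62 to 8.15). Endothelial and mural markers had no UMI in the 64 mixed cells of irradiated at 6 h. Vtn, a mural marker, was raised in the mixed cluster over all libraries, so its UMIs came from mixed cells of the other libraries. Microglia markers were at 0.196 times (0.187 to 0.205) the UMIs per microglia-like cell, and what this means for the explanations was not tested. The median mitochondrial share of the mixed cells was 1.49 times that of microglia-like cells, and free RNA, other brain cells carrying free microglial RNA, and damaged or mixed microglia stay open.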

How the results depend on the processing

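Settings that used the sham library of the other time, left out the most abundant member of a list, or left out Gtse1 and Psrc1 were chosen only after the results were seen. No paired analysis was possible because each group was 1 library and no test was run. Over the planned settings 394 of 400 list medians and 1091 of 1159 values of named genes stayed within their intervals, 6 and 66 moved outside them, and 2 genes reversed: Apoe at 1 week was at -0.055 over all barcodes and Lig1 at 1 week at -0.024 over thinned cells. The p53 median ranged from 1.95 to 2.33 at 6 h and from 1.14 to 1.30 at 1 week, and the homeostatic median at 6 h from -0.46 to -0.39. Scaling moved the median of all genes by less than 0.1. With members from 200 UMIs the 1 week medians were 0.23 for S phase and 0.45 for G2/M, a setting that leaves fewer, more abundant genes, and from 20 UMIs G2/M was at 2.26.

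With the sham library of the other time, 27 of 40 list medians and 53 of 145 gene values stayed within their intervals. A change of sign counts as reversed only where the main interval excluded 0. At 6 h the medians moved to 1.48 for interferon, -0.10 for S phase and -0.054 for G2/M, and oxidative phosphorylation reversed to 0.032. At 1 week they moved across 0 to 0.34 for the inflammatory list (main interval -0.40 to 0.05) and to 0.70 for G2/M, and reversed to -0.63 for interferon, -0.081 for MHC class I, 0.29 for immediate early, -0.040 for oxidative phosphorylation and 0.050 for TGF-beta. Genes that reversed at 6 h were Il1b (-0.60), Apoe (0.77), Top2a (0.80), Rrm2 (at least 2.22), Xist (-0.14) and Pgk1 (0.81). At 1 week they were Ccl4 (0.74), Ccl3 (0.51), Il1b (1.12), Apoe (-1.03), H2-K1 (-0.031), H2-Q7 (-0.65), Ifitm3 (-1.005), Oasl2 (-1.33) and Id2 (0.84). These follow from the sham libraries' own differences.

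Shares of cells moved in 58 of 88 planned values, including every change of the limit. At the 99th sham percentile the 6 h shares were 42.1% for p53, 6.48% for homeostatic, 9.13% for inflammatory and 3.19% for interferon, and at 1 week 10.9, 1.14, 0.247 and 2.32%. Without thinning they were 75.6% for p53, 12.5% for homeostatic and 21.98% for inflammatory at 6 h, and 3.39% for homeostatic at 1 week. Without the most abundant member they were 97.6% for p53, 28.6% for homeostatic and 18.6% for inflammatory at 6 h, and 68.9% for p53, 1.68% for homeostatic and 6.92% for interferon at 1 week. Cell cycle shares are given as sham and irradiated at 6 h, then sham and irradiated at 1 week. For G2/M they were 30.7, 29.0, 26.9 and 26.2% from 2 UMIs, 1.61, 1.46, 0.514 and 2.27% from 5 UMIs, and 30.7, 33.6, 26.6 and 25.9% unthinned. For S phase they were 32.8, 29.2, 28.9 and 33.9% from 2 UMIs, 2.13, 0.864, 1.69 and 3.56% from 5 UMIs, and 35.5, 31.7, 31.8 and 32.6% unthinned. Under the stricter cell filter microglia-like cells made up 99.6% of sham and 98.7% of irradiated cells at 6 h and 99.9% of irradiated cells at 1 week. The cause of these moves was not tested. Genes with few UMIs, such as Nusap1 and Il1b, have wide intervals at this depth.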

Other observations

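The hypothesis on dividing cells below was tested with a prediction written before its result was seen, whereas the genes singled out in the first paragraphs were read from the fixed lists. The complement and phagocytosis list was at -0.096 at 6 h, at percentile 13.7, with 1 of 25 members at least 1.5-fold lower and 5 higher, among the latter the anaphylatoxin receptor genes C5ar1 at 1.76 (1.67 to 1.85) and C3ar1 at 1.32 (1.24 to 1.40). At 1 week its median was 0.16, with 3 of 24 members higher and 0 lower. Gas6 and Pros1, ligands of the receptors Axl and Mertk that bind dying cells, stood at 0.36 (0.28 to 0.45) and 0.90 (0.82 to 0.97) at 6 h and at 0.93 (0.83 to 1.02) and 0.74 (0.64 to 0.84) at 1 week. The lysosome list was at 0.11 at 6 h, with 7 of 40 members higher and the sialidase gene Neu1 at 1.02 (0.88 to 1.16), and at 0.035 at 1 week with 0 of 40 members past 1.5-fold. The cholesterol and lipid list was at 0.26 at 6 h, with 6 of 25 members higher and 0 lower, and at 0.10 at 1 week with 4 of 21 higher and 1 lower. Ch25h, the enzyme that makes 25-hydroxycholesterol, had 4 UMIs in sham and 71 in irradiated cells at 6 h, a log2 fold of 4.58 (3.16 to 6.50), and Fabp3 was at 2.64 (1.93 to 3.41).

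Cell death and repair genes were mixed. The apoptosis list was at 0.12 at 6 h (7 of 30 members higher, 2 lower) and 0.16 at 1 week (6 higher, 1 lower), and it shares members such as Bax and Fas with the p53 list, while the survival gene Bcl2l1 was at 1.61 (1.48 to 1.73) and 0.70 (0.52 to 0.87). The DNA repair list was at -0.093 (4 of 37 higher, 3 lower) and 0.12 (3 higher, 0 lower), with the checkpoint kinase gene Chek2 at 1.52 (1.21 to 1.83) and 0.92 (0.41 to 1.44) and the ligase gene Lig1 at -1.28 (-1.87 to -0.72) at 6 h. Chek2 was at -0.72 (-1.24 to -0.22) between the sham libraries. Its level in irradiated cells at 1 week (15.3 CPM) was close to that of sham at 6 h (13.4 CPM). The senescence list was at 0.49 (7 of 14 higher, 2 lower) and 0.16 (5 of 14 higher, 1 lower), and its highest members at 6 h were Gdf15 and Cdkn1a. TGF-beta signalling was at 0.027 and -0.068, with 2 of 15 higher and 1 lower at 6 h and 0 of 13 higher and 1 lower at 1 week, and Bambi was at -1.60 (-2.76 to -0.58) at 6 h. Glycolysis was at 0.053 (1 of 20 higher, 2 lower) and -0.14 (0 higher, 2 lower), with the glucose transporter gene Slc2a1 at 0.85 (0.65 to 1.05) at 6 h. Oxidative phosphorylation was at -0.063 and 0.052 with 0 of 46 members past 1.5-fold at either time. Translation was at 0.11 and -0.13, and only Rps19 of its 44 members passed 1.5-fold, at 0.64 (0.61 to 0.67) and 0.83 (0.79 to 0.87).

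Immediate early genes, which cell dissociation can induce, were at 0.0063 at 6 h (5 of 40 higher, 7 lower) and -0.19 at 1 week (10 of 38 lower, 0 higher), but 0.56 between the sham libraries, with 17 of 39 members higher in sham at 1 week. Klf2 at -1.24 (-1.31 to -1.18), Klf4 at -1.36 (-1.56 to -1.16), Atf3 at -1.20 (-1.33 to -1.06) and Hspb1 at -1.55 (-1.87 to -1.23) were among the lowest genes at 1 week, and they were 0.82, 1.21, 1.18 and 1.31 higher in sham at 1 week than in sham at 6 h. Id2, a helix-loop-helix regulator gene in the same list, was at 2.61 (2.50 to 2.72) at 6 h. Ramp1, a receptor activity modifying protein gene, was lower at both times, at -1.36 (-1.54 to -1.19) and -1.15 (-1.32 to -0.97). Of the sex-linked list only Xist had enough UMIs, at 0.038 and 0.34.

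A hypothesis was that the cells with cell cycle genes at 1 week were those without a p53 response. Of 45 irradiated cells at 1 week with 5 or more G2/M UMIs, Gtse1 and Psrc1 not counted, 8 had no Cdkn1a UMI, a share of 17.8% (8.00 to 32.1%), where the prediction needed more than 50%. The share was 13.8% in the other irradiated cells. Cdkn1a had a median of 2 UMIs in these cells and 3 in the others, with means of 3.22 and 4.52. The share argues against cells without a Cdkn1a UMI as the main carriers of the cell cycle genes. Free RNA may have given a part of these UMIs, and its gauge rests on few cells: P2ry12 averaged 0.5 UMIs in the 2 monocyte-like cells of that library, against 25.01 UMIs in its microglia-like cells. The 1 border macrophage-like cell had 58 P2ry12 UMIs. Its P2ry12 (7912 CPM) and Tmem119 (2046 CPM) lay near the microglia-like levels (6967 and 3027 CPM), so that cell cannot gauge free RNA. No class at 1 week was known to lack Cdkn1a, and a weaker response in the dividing cells stays open.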
